A study of Homo sapiens with 16 samples.

How the data were processed

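Gene expression was measured in H1 human embryonic stem cells without or with BMP4 on 8 days, with 16 Illumina bead arrays, 1 per arm and day. Per the labels' protocols, RNA was isolated with Trizol, treated with DNase, and turned into biotinylated cRNA with a TotalPrep amplification kit. The scanner, its software and the normalization are not given in the sources used here.

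The values used are the deposited intensity values of the series' value table, on a linear scale. Read from the values themselves, the authors' intensities had been quantile normalized: all 16 arrays have the same median of 128.3 and quantiles that differ by at most 0.00201 on the log2 scale, with a highest value of 28353 and no sign of background subtraction. A table of non-normalized signals was also deposited. Its 32 columns of signals and detection p-values carry sample numbers that match no label, so they were given to no sample and not used here. The intended method, neqc with detection p-values, needs those columns and could not be run.

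In its place the background was estimated from the deposited intensities. Values below the main peak at 117.5 were mirrored about it, which gave a background SD of 7.74, and the 99th percentile of the mirrored values, 134.7, served as the detection floor in place of a detection p. Intensities were corrected by the normexp model (limma 3.58.1 in R 4.3.3) with that background, an offset of 16 was added and log2 was taken. The offset pulls in the changes of dim genes. A probe was kept if it lay above the floor on at least 3 arrays. On each array 42.2% of the probes lie above the floor, a share the quantile normalization fixes. Where no array of an arm in a window lay above the floor, or the arm's mean lay under it, the change is given as "at least N-fold", from the mean of the bright arm against the mean of the higher of the floor and the probe's own value. Differences between windows and at day 0 are given without such a bound, and they are not exact for genes near the floor.

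Of 47323 probes 30113 have 1 gene symbol in the platform annotation, 8 have several and 17202 have none there. Through gene identifiers 30074 were matched to the current reference table, and 0 symbols changed. Each of the 20046 genes with a named probe was represented by the probe with the highest mean log2 value, and 13339 passed the filter, 3538 of them with more than 1 detected probe. For some named genes a dimmer probe gave a late log2 change that differed by over 1 from the value used: TFAP2A 1.00 on both of its dimmest probes, KRT16P2 4.70, TBXT 1.62, HEY1 2.97, HAPLN1 2.44, TNFRSF19 1.27, TBX3 2.33, NPTX1 -1.35 and -1.14, RTEL1 -0.16 and PSMB8 -0.26. The other such genes are given with their values in the text.

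Arms and days came from the labels. All arrays entered 1 limma fit with a mean for each arm and window (day 0, days 1 to 3, days 4 to 7) and empirical Bayes moderation with an intensity trend. From it came the early effect, the late effect, the difference between them and the drift of untreated cells. The effect over days 1 to 7 and the course (natural spline with 3 degrees of freedom, F test of the arm and interaction terms) were fitted likewise. Adjusted p-values are Benjamini-Hochberg values from limma over all tested genes, and 0.05 was the threshold. All tests are two-sided. The 25 gene lists (pluripotency, BMP and SMAD targets, FGF and ERK feedback, Wnt feedback, trophoblast, placental hormones, extravillous trophoblast, amnion, primitive streak, lateral and cardiac mesoderm, endoderm, neural ectoderm, neural crest, surface ectoderm, blood and endothelium, extracellular matrix, basement membrane, epithelial and mesenchymal state, cell cycle, cell cycle inhibitors, hypoxia and glycolysis, stress response, interferon and MHC class I, HOX and housekeeping genes) were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Members with no named probe or below the filter were not analysed here.

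The lists, fits, alternatives and the rule for naming genes were fixed before the data were examined, and the background estimate that replaced the intended method was chosen after. Named were POU5F1, NANOG and SOX2; for the early and the late effect the 12 largest rises and 8 largest falls past the threshold whose arrays did not overlap between the arms; for the difference and the drift the 5 largest each way; for day 0 the 5 largest each way among genes detected on both arrays; for each list the 3 members with the largest late change past the threshold; and for the first 5 lists the same for the early change. Had a list no such member, 1 member with the largest late change would have been named. Other members are named as examples of their list or because a count was small. Subtraction of the day 0 difference was added after the day 0 arrays had been seen, and its error is larger because it rests on 1 array per arm.

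The fits were tested on simulated arrays with the means and spreads of the 13339 genes, 200 of them changed. Noise was independent for each array, with no dependence between days and no offset between the arms. Such features were therefore not tested. With 200 genes changed, unchanged genes gave 4 to 12 false calls per comparison. All real comparisons but the drift called far more genes than 200. False calls and recovery depend on the share of changed genes, so these values do not carry over to them. For the early effect 85.1% of 2-fold and 100% of 4-fold changes were recovered, for the late effect 91.0% and 100%, for the difference 43.3% and 95.5%, for the drift 86.6% and 98.5%, for the effect over days 1 to 7 97.0% and 100%, and for the course, with the fold reached at day 7, 44.8% and 98.5%. Of 1.5-fold changes 20.9% were recovered in the early and 49.2% in the late window. Untreated arrays correlated with one another at 0.964 to 0.992 over genes, and no columns were identical.

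Alternatives were the deposited values on the log2 scale without background correction, another scaling, no filter or a looser one, the mean of a gene's probes, no intensity trend, array weights, day as a block, other windows, a linear day term, fits of only the arrays compared, a smaller spline and leaving out each array in turn. Added after the data were seen were an offset of 50, centring on the housekeeping list, subtraction of day 0, a test of the shape of the course alone, leaving out both day 7 arrays, and the unnamed probes.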

Results

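H1 cells, an established line of human embryonic stem cells, were grown on a Matrigel coating in mTeSR medium with no added factor or with bone morphogenetic protein 4 (BMP4, a ligand of the TGF-beta family that signals through SMAD1, SMAD5 and SMAD8) at 100 ng/ml. Total RNA was profiled on Illumina bead arrays. The series holds 16 arrays, 1 for each arm on each of 8 days numbered 0 to 7, so each arm has 8 arrays. Its title points to the regulatory module of NANOG, OCT4 (POU5F1) and SOX2, the transcription factors that maintain pluripotency. The comparison of the arms asks how the transcriptome of these cells moved under BMP4. No day was measured more than 1 time per arm, and the labels do not say how many cultures the arrays come from. Neighbouring days were therefore pooled into an early window (days 1 to 3, n = 3 arrays per arm) and a late window (days 4 to 7, n = 4 arrays per arm), and p-values measure the spread between days and arrays, which may be technical and includes any trend within a window. After the filter on dim probes 13339 genes were tested. The number of arrays limits the precision of every value.

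In the early window BMP4 raised direct targets of its own pathway, and MSX1, EOMES, HAND1 and MIXL1 were among the genes that rose most. MSX1, a homeobox target of BMP signalling, was 30.1-fold higher than in untreated cells (log2 change 4.91, SE 0.29, adjusted p = 8.35e-09), and the streak T-box gene EOMES was 31.1-fold higher (log2 change 4.96, SE 0.70, adjusted p = 7.57e-05). HAND1, a basic helix-loop-helix factor of trophoblast and lateral mesoderm, rose 42.0-fold (log2 change 5.39, SE 0.73). The streak homeobox gene MIXL1 rose at least 19.4-fold. TFAP2A, a regulator of trophoblast and surface ectoderm, rose by 4.64 on the log2 scale, and the Notch target HEY1 rose at least 17.2-fold. A set of genes not above background in untreated cells on days 1 to 3 gave only lower bounds. Brachyury (TBXT, adjusted p = 6.03e-06) was at least 33.5-fold higher, the trophectoderm and posterior gene CDX2 at least 14.5-fold (adjusted p = 2.36e-07), and the Wnt ligand gene WNT5B at least 16.5-fold (adjusted p = 6.10e-07). The prostaglandin transporter gene SLCO2A1 rose 25.3-fold, and HPGD, which encodes a prostaglandin-degrading enzyme, was at least 21.3-fold higher. The probe named for the keratin pseudogene KRT16P2 was at least 43.8-fold higher, and its assignment is uncertain because related keratin transcripts are nearly identical.

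Of the pluripotency trio, SOX2 fell in the early window by 1.54 on the log2 scale (2.92-fold, SE 0.28, adjusted p = 5.48e-04). POU5F1 (log2 change 0.10, SE 0.20, adjusted p = 0.737) and NANOG (log2 change 0.32, SE 0.24, adjusted p = 0.354) did not pass the test. The largest early falls were in NPTX1, which encodes a neuronal pentraxin (26.6-fold lower, log2 change -4.74, SE 0.38), STC1, encoding the secreted glycoprotein stanniocalcin 1 (8.36-fold), IGFBP2 (6.08-fold), the Wnt antagonist gene SFRP1 (6.02-fold), LRIG1, a negative regulator of receptor tyrosine kinases (5.65-fold), and CLC (5.41-fold). AKAP1 and CFAP96 were at least 3.64-fold and at least 2.97-fold lower. IGFBP2 and NPTX1 were already lower in the BMP4 arm at day 0 (log2 differences of -2.72 and -2.40). With the day 0 difference subtracted, IGFBP2 turned to 0.11 and NANOG to -0.68, and NPTX1 (-2.33, adjusted p = 0.111), SOX2 (-1.46, adjusted p = 0.170), CLC (-1.78, adjusted p = 0.170) and CFAP96 (-1.21, adjusted p = 0.214) no longer passed.

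Among 14 tested targets of BMP and SMAD signalling 11 rose early and none fell, with a median log2 change of 2.61 (camera adjusted p = 3.93e-14, and adjusted p = 0.00107 with an estimated correlation). MSX1, DLX5 (at least 11.2-fold) and the inhibitory SMAD gene SMAD6 (11.6-fold) rose most, and ID1 rose by 2.88 on the log2 scale. DLX5 did not pass with the day 0 difference subtracted (3.72, adjusted p = 0.0625). In the list of Wnt feedback genes 8 of 10 rose, led by SP5 (at least 12.9-fold), DKK1 (7.28-fold) and LEF1 (4.29-fold), and none fell (camera adjusted p = 1.63e-05, and adjusted p = 0.174 with an estimated correlation). With the day 0 difference subtracted 1 member passed, and SP5 (3.09, adjusted p = 0.185), DKK1 (2.33, adjusted p = 0.168) and LEF1 (0.91, adjusted p = 0.476) did not. Of 18 trophoblast regulators and keratins 13 rose and none fell, among them HAND1, TFAP2A, HEY1, GATA2 (at least 5.40-fold) and GATA3 (at least 5.15-fold), with adjusted p = 0.189 with an estimated correlation. In the primitive streak and early mesoderm list 10 of 15 rose, including WNT3 (at least 11.3-fold), MESP1 (at least 9.25-fold) and CER1 (log2 change 2.96), with adjusted p = 0.484 with an estimated correlation. Of 14 genes of lateral and cardiac mesoderm 6 rose, with adjusted p = 0.444 with an estimated correlation. The hypoxia and glycolysis list had 8 of 14 members lower and 1 higher, ANKRD37 being 4.45-fold lower, with adjusted p = 0.444 with an estimated correlation. The median of that list was already -0.67 on the log2 scale at day 0, and its camera call was lost with day 0 subtracted (adjusted p = 0.989). In the pluripotency list 6 of 26 fell, such as SOX3 (4.39-fold), and 4 rose: NODAL (14.8-fold) and LEFTY2 (4.55-fold), which belong to the Nodal pathway, GDF3 (5.10-fold) and DPPA2. None of these rises passed with the day 0 difference subtracted (LEFTY2 0.92, adjusted p = 0.685, and GDF3 0.68, adjusted p = 0.681). In the FGF and ERK feedback list 4 of 13 rose, including IER3 (3.22-fold), and 2 fell, DUSP6 (2.33-fold) and DUSP4 (at least 1.58-fold), and with the day 0 difference subtracted neither passed (DUSP6 -0.0417, adjusted p = 0.976, and DUSP4 0.59). No camera call was made for the other lists early, the lowest adjusted p being 0.0587 for HOX genes, of which 5 of 12 rose. Some of these lists gained a call under an alternative. The pluripotency list did with day 0 subtracted (median -0.67, adjusted p = 0.0221) and without BMP4 day 1 (-0.44, adjusted p = 0.0151). HOX genes (adjusted p = 2.59e-04) and the amnion list (1.02, adjusted p = 0.00535) did without BMP4 day 1, the amnion list without BMP4 day 2 (adjusted p = 0.0460) or with the mean of probes (adjusted p = 0.0228), and HOX, amnion and basement membrane lists without untreated day 3 (adjusted p = 0.0403) or without the filter on dim probes (adjusted p = 0.00666 to 0.0334). HOX genes also gained it with a looser filter (adjusted p = 0.0248).

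In all, 3930 genes differed between the arms in the early window by limma at an adjusted p under 0.05, 2155 higher and 1775 lower with BMP4, and 929 of them by at least 2-fold (552 higher, 377 lower). With the difference between the day 0 arrays subtracted, 316 genes passed (143 higher, 173 lower), and 456 of the 929 kept a change of at least 2-fold in the same direction. EOMES (log2 change 5.04, adjusted p = 0.0680), MIXL1 (4.08, adjusted p = 0.25) and NODAL (2.10, adjusted p = 0.351) did not pass then. Of the lists above, 8 BMP and SMAD targets, 7 trophoblast, 2 streak and 2 lateral and cardiac mesoderm genes rose after that subtraction, 2 pluripotency genes and 1 HOX gene fell, no HOX or pluripotency gene rose, and no hypoxia gene passed. Where arrays were centred on the housekeeping list, 68.2% of the early calls were higher with BMP4, against 54.8% here. With the window set to days 1 to 2 alone, 2360 genes passed, and LEFTY2 did not (adjusted p = 0.109). Adjusted over the list alone, the early counts of higher and lower genes were 12 and 0 for the BMP and SMAD targets, 9 and 0 for Wnt feedback, 14 and 0 for trophoblast, 10 and 0 for the streak, 6 and 0 for lateral and cardiac mesoderm, 2 and 8 for hypoxia, 4 and 7 for pluripotency, 5 and 2 for FGF and ERK feedback and 6 and 0 for HOX genes.

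In the late window the cells of the BMP4 arm carried higher levels of HAND1, PITX1, ISL1 and MSX1 than untreated cells, and lower levels of SOX2, SOX3, SOX21 and OTX2. HAND1 was 165-fold higher (log2 change 7.37, SE 0.64, adjusted p = 6.75e-08), the apelin receptor gene APLNR 142-fold (log2 change 7.15, SE 0.85, adjusted p = 2.46e-06), the hindlimb and pituitary homeobox gene PITX1 133-fold (log2 change 7.06, SE 0.57, adjusted p = 3.20e-08) and ISL1, a LIM homeobox factor of cardiac progenitors and amnion, 89.2-fold (log2 change 6.48, SE 0.54, adjusted p = 4.34e-08). The KRT16P2 probe was at least 52.9-fold higher. Neuropeptide Y (NPY) rose 68.3-fold, MSX1 68.1-fold and the hyaluronan link protein gene HAPLN1 55.5-fold. NPY was already higher in the BMP4 arm at day 0, with a log2 difference of 2.10 from an untreated array on which it was not above background. TCIM, the posterior gene HOXB8 and the zinc transporter gene SLC39A2 were not above background in untreated cells and were at least 36.2-fold, at least 34.4-fold and at least 25.5-fold higher. UGT2B11, whose probe may also read other members of the UGT2B family, rose at least 33.9-fold.

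SOX2 fell 12.9-fold in the late window (log2 change -3.69, SE 0.24, adjusted p = 4.44e-09), and its second probe gave a log2 change of -4.05. POU5F1 fell 2.20-fold (log2 change -1.14, SE 0.17, adjusted p = 2.48e-05). With the day 0 difference subtracted SOX2 still passed (log2 change -3.60, adjusted p = 6.78e-04), and POU5F1 did not (-0.84, adjusted p = 0.129). NANOG did not pass the test on its brighter probe (log2 change -0.28, SE 0.21, adjusted p = 0.275), while its dimmer probe gave -0.97 and the mean of both probes passed (log2 change -0.63, adjusted p = 0.00979). In untreated cells NANOG itself went from a log2 level of 8.20 on day 1 to 7.25 on day 7, a drift that did not pass the test (adjusted p = 0.314 for days 4 to 7 against days 1 to 3). Further large falls against untreated cells were in SHISA2 (20.1-fold), SOX21 (18.8-fold), LRIG1 (16.3-fold), SOX3 (14.1-fold), the tryptophan-degrading enzyme gene IDO1 (12.8-fold) and the forebrain and epiblast homeobox gene OTX2 (12.8-fold). Part of these gaps arose in untreated cells. From day 1 to day 7 SHISA2 went from 8.81 to 11.04 there, SOX21 from 9.06 to 11.07 and OTX2 from 7.86 to 9.38. Untreated LRIG1 went from 9.62 to 10.06, IDO1 from 9.74 to 9.64 and SOX3 from 10.05 to 9.29. Under BMP4 SHISA2 went from 7.39 to 6.07, SOX21 from 8.88 to 6.35 and OTX2 from 6.675 to 5.21. SOX3 was already lower at day 0 (log2 difference -1.81) and did not pass with that subtracted (adjusted p = 0.0612). NPTX1 was not above background under BMP4 and was at least 22.2-fold lower.

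**Figure D1:**
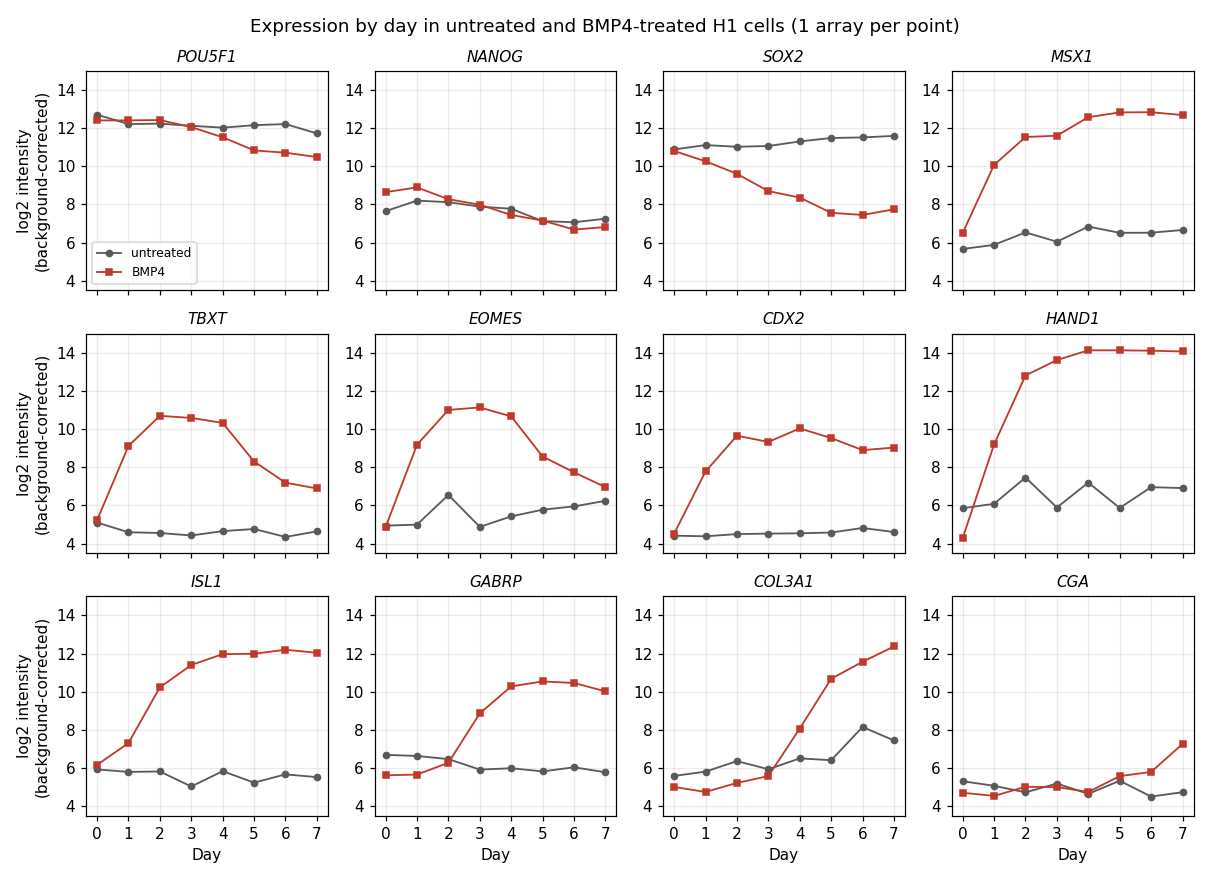
Background-corrected log2 intensity (y axis) by day (x axis) for 12 genes in untreated cells (grey circles) and BMP4-treated cells (red squares); each point is 1 array, so there are no error bars. SOX2 in the BMP4 arm goes from 10.8 at day 0 to 7.75 at day 7, TBXT is highest at day 2 (10.7), HAND1 reaches 14.1 from day 4, and CGA stands apart from the untreated arm at day 7 (7.26 against 4.74).

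Of 26 tested pluripotency genes 20 fell late, 3 rose and 3 did not pass (median log2 change -1.30, camera adjusted p = 6.07e-07, and adjusted p = 0.295 with an estimated correlation). USP44 (log2 change -3.07), FGF2 (-2.08) and the de novo DNA methyltransferase gene DNMT3B (-1.81) fell with SOX2 and SOX3. The genes that rose were LEFTY2 (log2 change 4.00), NODAL (at least 2.04-fold) and GDF3 (2.05-fold), all of the Nodal and GDF branch of signalling. At day 0 the median of this list was 0.45 higher in the BMP4 arm, and with the day 0 difference subtracted 15 members fell and none rose.

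The targets of BMP and SMAD signalling stayed high: 13 of 14 rose and none fell (median log2 change 2.43, camera adjusted p = 3.06e-10, and adjusted p = 0.00404 with an estimated correlation), with MSX1, DLX5 (27.4-fold) and SMAD6 (21.7-fold) in front, and with the day 0 difference subtracted 12 rose. All 10 Wnt feedback genes rose, such as DKK1 (22.9-fold), LEF1 (11.2-fold) and TNFRSF19 (9.37-fold), with adjusted p = 0.146 with an estimated correlation. This list was 0.47 higher at day 0 in the BMP4 arm, and 3 members passed with that difference subtracted. In the FGF and ERK feedback list 7 of 13 rose, including SPRED2 (4.54-fold) and IER3 (3.79-fold), and 3 fell, among them EGR1 (5.60-fold), and camera made no call for the list (adjusted p = 0.139) but did with day 0 subtracted (median 0.39, adjusted p = 0.0406).

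Of 18 trophoblast regulators and keratins 16 rose and 1, TEAD1, fell (median log2 change 2.38, camera adjusted p = 1.39e-08, and adjusted p = 0.146 with an estimated correlation). HEY1 (26.6-fold), CDX2 (at least 19.9-fold), GATA2 (at least 7.49-fold), GATA3 (at least 5.51-fold), PPARG (at least 7.56-fold) and the simple-epithelium keratin genes KRT8 (log2 change 2.38), KRT19 (2.38) and KRT7 (1.27) were among them. Products of mature placenta were mostly not measurable. Of 33 named genes in the list of placental hormones and syncytiotrophoblast 12 passed the filter, 4 rose and none fell (camera adjusted p = 0.129, and adjusted p = 0.0488 with day 0 subtracted). These were placental growth factor PGF (4.26-fold), the glycoprotein hormone alpha subunit CGA (at least 1.65-fold, adjusted p = 0.0216), PSG4 (at least 1.43-fold), whose probe may read other members of the PSG family and whose change was -0.09 with day 0 subtracted, and CYP11A1 (log2 change 0.90). The CGA call was lost without BMP4 day 7 (log2 change 0.57, adjusted p = 0.0708), untreated day 4 (log2 change 0.99, adjusted p = 0.0525) or untreated day 6 (log2 change 0.94, adjusted p = 0.0629), and with the day 0 difference subtracted (log2 change 1.64, adjusted p = 0.161). In the extravillous trophoblast list 2 of 8 rose, the integrin gene ITGA5 (6.56-fold) and the gelatinase gene MMP2 (at least 2.46-fold), while HLA-G had a log2 change of -0.07 (camera adjusted p = 0.0991). In the amnion list 10 of 11 rose, including ISL1, GABRP (21.3-fold), IGFBP3 (log2 change 4.39) and VTCN1 (at least 8.04-fold), with adjusted p = 0.146 with an estimated correlation.

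In the lateral and cardiac mesoderm list 13 of 14 rose, with a median log2 change of 3.09 (camera adjusted p = 2.80e-08, and adjusted p = 0.146 with an estimated correlation), led by SNAI2 (35.4-fold), TBX3 (at least 21.6-fold) and HAND2 (at least 15.6-fold). In the streak list 11 of 15 rose (adjusted p = 0.364 with an estimated correlation), with MESP1 at least 11.7-fold higher, TBXT at least 8.68-fold and WNT3 at least 6.39-fold. These levels passed a maximum within the course. TBXT in the BMP4 arm was at 10.7 on day 2 and 6.89 on day 7 on the log2 scale, and EOMES at 11.1 on day 3 and 6.95 on day 7. HOX genes rose in 8 of 12 cases, HOXB2 by at least 18.3-fold and HOXB5 by 26.1-fold (adjusted p = 0.281 with an estimated correlation). Of 7 blood and endothelial genes 6 rose, such as LMO2 (4.00-fold), the angiopoietin receptor gene TEK (3.03-fold) and ESAM (at least 1.89-fold), with adjusted p = 0.364 with an estimated correlation, and none of them passed with the day 0 difference subtracted. The call of that list (camera adjusted p = 0.0343) was lost without BMP4 day 7 (adjusted p = 0.0502), with day 0 subtracted (adjusted p = 0.0617), with housekeeping centring (adjusted p = 0.0693) and with a looser filter (adjusted p = 0.0796). Of 12 endoderm genes 6 rose, including SOX17 (at least 9.96-fold), CXCR4 (12.5-fold) and GATA4 (at least 4.33-fold), and 2 fell (camera adjusted p = 0.0858, adjusted p = 0.0465 with day 0 subtracted and adjusted p = 0.0160 without the filter on dim probes).

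In the fibroblast and extracellular matrix list 13 of 15 rose and 1, THY1, fell, with LUM (37.3-fold), COL5A1 (13.8-fold) and COL6A3 (13.6-fold) in front (adjusted p = 0.295 with an estimated correlation). In the basement membrane list 9 of 10 rose, led by COL4A1 (4.95-fold), COL4A2 (3.65-fold) and LAMB1 (2.90-fold), with adjusted p = 0.285 with an estimated correlation. A second, dimmer probe of LAMB1 gave a log2 change of 0.32. Of 11 genes of the epithelial and mesenchymal state 7 rose, among them SNAI2, TWIST1 (at least 8.44-fold) and ZEB2 (3.33-fold), and 1 fell, CLDN6 (adjusted p = 0.178 with an estimated correlation, and the camera call was lost with the mean of probes, adjusted p = 0.0608). The epithelial cadherin gene CDH1 had a log2 change of -0.27.

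Camera made no late call for the neural list (5 of 12 lower, 1 higher, median log2 change -0.60, adjusted p = 0.159), and its median difference between arrays of the same day went from 0.42 on day 1 to -1.15 on day 7. OTX2 was lower 12.8-fold and SIX3 at least 7.58-fold, and NCAM1 was higher 6.44-fold. In the neural crest list 4 of 8 rose, including EDNRB (7.08-fold) and SOX9 (3.70-fold), and 2 fell, FOXD3 (at least 1.76-fold) and SOX10 (camera adjusted p = 0.459). EDNRB had a log2 difference of 3.14 between the arms at day 0 already, and its late change was -0.32 with that difference subtracted. EDNRB was not above background on the untreated day 0 array, so neither value is exact. Of 9 genes of surface ectoderm and keratinocytes 5 rose, such as DSP (2.51-fold), GRHL2 (1.93-fold) and DSC3 (1.75-fold), and none fell (camera adjusted p = 0.177). GRHL2 turned to -0.31 on the log2 scale with day 0 subtracted and did not pass on days 6 to 7 alone (adjusted p = 0.0667).

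Of 25 cell cycle genes 12 fell, such as BUB1 (2.96-fold) and BUB1B (2.36-fold), and 2 rose, RRM2 (3.49-fold) and CDC20 (adjusted p = 0.364 with an estimated correlation). Of 10 inhibitors of the cell cycle 8 rose, including GADD45G (4.57-fold), CDKN2B (at least 3.07-fold) and CDKN1C (3.31-fold), and BTG1 fell (adjusted p = 0.295 with an estimated correlation). GADD45G had a log2 difference of 1.60 at day 0 already, and with day 0 subtracted 3 members passed, without GADD45G (0.59, adjusted p = 0.563), CDKN2B (1.74, adjusted p = 0.120) and CDKN1C (1.63, adjusted p = 0.0867). In the hypoxia and glycolysis list 8 of 14 fell, such as ADM (3.69-fold), ANKRD37 (2.95-fold) and HK2 (2.66-fold), and 2 rose, NDRG1 (2.59-fold) and SLC2A3 (camera adjusted p = 0.0447, and adjusted p = 0.364 with an estimated correlation). The camera call was lost without untreated day 7 (adjusted p = 0.132), BMP4 day 4 (adjusted p = 0.0831) or BMP4 day 5 (adjusted p = 0.0548). With the day 0 difference subtracted the median was 0.0426, with 2 genes higher and 1 lower, and ANKRD37 turned to 0.0867. The stress response list had 6 of 15 higher, led by TRIB3 (3.88-fold) and DDIT3 (2.31-fold, but adjusted p = 0.0512 without untreated day 5, 0.0524 without background correction and 0.0962 on days 6 to 7), and HSPA1A lower (2.33-fold), with camera adjusted p = 0.347. The list of interferon and MHC class I genes had 5 of 16 higher and 4 lower (camera adjusted p = 0.849): the immunoproteasome gene PSMB8 fell 4.50-fold and the peptide transporter gene TAP1 2.43-fold, whereas B2M rose 2.40-fold. Of 12 housekeeping genes 6 fell, including HPRT1 (2.15-fold) and TFRC (1.59-fold), and 2 rose, including YWHAZ (1.75-fold), whose second probe gave -0.44 on the log2 scale and whose call was lost with the mean of both (adjusted p = 0.228). The list had a camera adjusted p of 0.225. The median of this list was -0.17 and became 0.00745 where arrays were centred on the list.

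Across all genes 7230 differed in the late window by limma, 3659 higher and 3571 lower with BMP4, and 2241 of them by at least 2-fold (1293 higher, 948 lower). With the day 0 difference subtracted 2612 passed (1197 higher, 1415 lower), and 1571 of the 2241 kept a change of at least 2-fold in the same direction. After that subtraction 14 trophoblast, 6 amnion, 2 streak, 9 lateral and cardiac mesoderm, 7 matrix, 6 basement membrane, 7 HOX and 3 endoderm genes rose, 1 HOX and 3 cell cycle genes fell, and no stress response gene passed. Of the genes named above, these also lost their late call then: LEFTY2 (adjusted p = 0.0664), EGR1 (adjusted p = 0.105), MESP1 (adjusted p = 0.154), SOX17 (adjusted p = 0.0524), COL6A3 (adjusted p = 0.0730), ZEB2 (adjusted p = 0.129), DSC3 (adjusted p = 0.307), RRM2 (adjusted p = 0.211), BUB1B (adjusted p = 0.116), ADM (adjusted p = 0.224), HK2 (adjusted p = 0.0502), TRIB3 (adjusted p = 0.0554), HSPA1A (adjusted p = 0.337), DDIT3 (adjusted p = 0.257) and YWHAZ (adjusted p = 0.131). Without background correction the changes of named genes were smaller, with late log2 changes of 6.39 for HAND1, 4.86 for ISL1 and -3.18 for SOX2. Centring on the housekeeping list moved the median of all genes by 0.18 and gave 66.8% higher calls, against 50.6% here. Adjusted over the list alone, the late counts of higher and lower genes were 7 and 4 for FGF and ERK feedback, 12 and 0 for the streak, 14 and 1 for extracellular matrix, 5 and 2 for surface ectoderm, 7 and 2 for the epithelial and mesenchymal state, 2 and 9 for hypoxia, 5 and 5 for interferon and MHC class I, 9 and 0 for HOX genes and 3 and 6 for housekeeping, and they equalled the counts over all genes for each of the other lists. Early and late calls shared 1692 higher and 1491 lower genes, where independent lists of those sizes would share 591 and 475. The 2 windows use different arrays, and a constant offset between the arms would enter both. Both tests also use the same residual spread of a gene, so the 2 sets of calls are not independent.

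**Figure D2:**
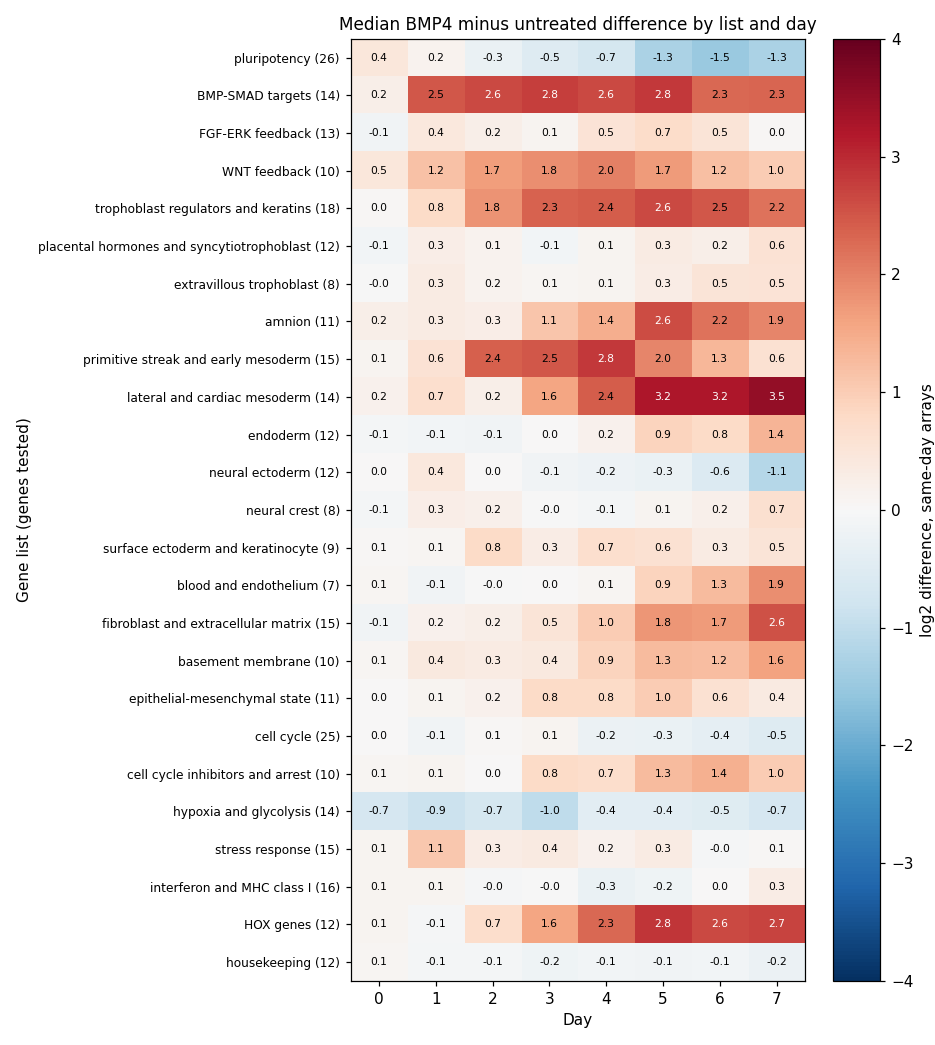
Heat map of the median log2 difference between the BMP4 and the untreated array of the same day (colour and printed value) for the 25 gene lists (rows, tested genes in brackets) by day (columns). The BMP and SMAD list is at 2.48 on day 1 and 2.34 on day 7, the streak list peaks at 2.81 on day 4 and is at 0.61 on day 7, and the lateral and cardiac mesoderm list is at 3.51 on day 7.

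The late effect was tested against the early one gene by gene. Another choice of the days gave a higher count. It also set late days against early ones, so it cannot settle whether chance was the source of the count. LUM, encoding the matrix proteoglycan lumican, had a late change larger than its early change by 4.75 on the log2 scale (SE 0.80, adjusted p = 0.00243). SLC39A2 (4.65), the atrial myosin light chain gene MYL4 (4.45, adjusted p = 4.57e-04), HOPX (4.41) and COL3A1 (4.40) followed. HOPX was not above background in either arm on days 1 to 3, nor was SLC39A2 in untreated cells, so these values of both genes are not exact. MYL4 was at least 26.5-fold higher late, HOPX at least 15.5-fold and COL3A1 11.7-fold. In the other direction stood SIX3 (-3.57, adjusted p = 0.00275), the cadherin gene CDH6 (-3.49), SOX21 (-2.94), the rhomboid-like gene RHBDL3 (-2.78) and NODAL (-2.60, adjusted p = 0.0405). CDH6 was 4.99-fold higher than in untreated cells early and 2.25-fold lower late. Between day 1 and day 7 its log2 level went from 5.65 to 8.86 in untreated cells and from 9.06 to 6.28 under BMP4. It was already 1.47 higher in the BMP4 arm at day 0. SOX2 (-2.14, adjusted p = 0.00275) and POU5F1 (-1.24, adjusted p = 0.00706) fell further late than early, and NANOG did not pass (-0.59, adjusted p = 0.267). Among the lists, 14 of 26 pluripotency genes had a lower late than early effect (adjusted p = 0.242 with an estimated correlation), 7 of 14 lateral and cardiac mesoderm genes a higher one, as had 6 of 15 matrix genes, 6 of 12 HOX genes, 5 of 10 basement membrane genes and 4 of 11 amnion genes, each also with adjusted p = 0.242 with an estimated correlation. Adjusted over the list alone these counts were 22, 12, 10, 7, 6 and 6, with 1 pluripotency gene higher and 1 HOX gene lower.

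The difference passed in 1237 genes, 660 with a higher and 577 with a lower late effect, against 1612 genes when days 5 to 7 were set against days 1 to 4, and 63.8% were higher with arrays centred on the housekeeping list, against 53.4% here. Single arrays moved this count by over 1.5 times: it was 693 without untreated day 1, 777 without untreated day 3, 678 without BMP4 day 2, 1892 without BMP4 day 3, 2404 without BMP4 day 4 and 776 without BMP4 day 6. The NODAL call was lost when any 1 of the untreated arrays of days 1 to 7 was left out (adjusted p = 0.0527 to 0.111) and without BMP4 day 2 (adjusted p = 0.118), day 5 (adjusted p = 0.0742), day 6 (adjusted p = 0.0865) or day 7 (adjusted p = 0.0747), as well as without the filter on dim probes (adjusted p = 0.0707) or the intensity trend (adjusted p = 0.0598).

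Over days 1 to 7 taken as 1 window (n = 7 arrays per arm) 7010 genes differed, 3681 higher and 3329 lower with BMP4 (52.5% higher, and 67.9% with housekeeping centring), and 366 passed with the day 0 difference subtracted. The course over all 8 days, fitted with splines, differed between the arms in 8262 genes by limma's F test. When a constant offset between the arms was allowed and only the shape was tested, 3620 genes passed. A first day from which the arms stayed over 2-fold apart to day 7, with BMP4 arrays outside the range of all untreated arrays, was found for 162 of 325 tested list genes, 122 rising and 40 falling. For 18 of them it was day 7, the last array, where nothing shows that the change lasted, and for 4 it was day 0. The median day was 1 for the 12 rising BMP and SMAD targets and for the 5 rising Wnt feedback genes, 1.5 for 14 trophoblast genes, 2 for 7 HOX genes, 3 for 7 amnion and 11 lateral and cardiac mesoderm genes, 5 for 12 matrix genes, and 5.5 for 6 blood and endothelial genes. It was 3.5 for the 16 falling pluripotency genes. For 3 of the 5 placental genes with a day it was day 7. These days have no replicate and no test.

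The drift of untreated cells, the change from days 1 to 3 to days 4 to 7 without BMP4, passed the test in 10 genes. On days 4 to 7 the forebrain homeobox gene SIX3 was higher than on days 1 to 3 by 3.25 on the log2 scale (SE 0.43, adjusted p = 0.00353), the LIM-domain gene LMO1 by 2.91 (adjusted p = 0.00224), the forebrain zinc-finger gene FEZF1 by 2.56 (adjusted p = 0.0154), the ephrin receptor gene EPHA4 by 2.37 (adjusted p = 0.0109) and VWF by 2.28 (adjusted p = 0.0109). The untreated means of SIX3, LMO1, FEZF1 and VWF on days 1 to 3 lay under the detection floor, so their differences are not exact. LHX5, FEZF1-AS1, PKDCC, CNTNAP2 and CITED2 were the others that passed, all 10 were higher late (49.2% of 183 genes with array weights, and 71.4% of 28 without untreated day 4), and these 5 were singled out after their values were seen. Of 12 neural genes 1 passed over all genes and 4 rose adjusted over the list alone (median 0.51, camera adjusted p = 2.73e-05, and adjusted p = 0.605 with an estimated correlation). Camera also called the hypoxia (adjusted p = 6.45e-04) and Wnt feedback (adjusted p = 0.0367) lists up. It called the pluripotency (adjusted p = 0.00259) and FGF and ERK feedback (adjusted p = 0.0256) lists down. None of these passed with an estimated correlation (adjusted p = 0.758 to 0.851). PAX6 had a log2 difference of 1.58 (adjusted p = 0.345). SIX3 in the BMP4 arm was at 4.70 on the log2 scale at day 0 and between 4.39 and 5.17 on days 1 to 7. Another split of the 7 untreated arrays gave 16 genes, so the splits do not exclude chance for this count. That split also set later days against earlier ones, so it cannot tell chance from a trend in time. At an unadjusted p under 0.05 there were 1003 genes. The count was 1 on values without background correction, where the log2 differences were 1.60 for SIX3 (adjusted p = 0.112), 1.39 for LMO1 (adjusted p = 0.0539), 1.08 for FEZF1, 1.52 for EPHA4 and 0.88 for VWF and none of these passed. With an offset of 50 FEZF1, EPHA4 and VWF did not pass (0.0509 to 0.0994). Leaving out 1 array moved it over 1.5 times for untreated day 1 (1), day 2 (2), day 3 (4), day 4 (28) and day 6 (3). The SIX3 call was lost without untreated day 1 (adjusted p = 0.0689) or day 2 (adjusted p = 0.0552), and the calls of FEZF1, EPHA4 and VWF without day 1 (0.117 to 0.147), day 2 (0.107 to 0.127), day 3 (0.0592 to 0.0662) or day 6 (0.0640).

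The day 0 arrays of the 2 arms differed from each other. The labels do not say whether BMP4 had been added when the day 0 sample of that arm was taken, and the difference, with 1 array on each side, was not tested. Where it was subtracted, its error came from the spread of arrays within the windows. The SD over genes of the log2 difference was 0.553, against 0.275 to 0.369 between untreated arrays of neighbouring days from day 1 to day 7. Between the untreated day 0 array and later arrays of its own arm it was 0.466 to 0.592, and 10933 genes were above background on it, against 11507 on the BMP4 day 0 array. In all, 1024 genes were at least 2-fold apart, 656 higher and 368 lower in the BMP4 arm. Among genes above background on both arrays the largest differences were in VENTX (2.82), ZNF121 (2.58), SNORD13 (2.40), GOLIM4 (2.39) and PLAAT4 (2.36) in one direction and in IGFBP2 (-2.72), the stress gene DDIT4 (-2.69), NPTX1 (-2.40), RTEL1 (-2.28) and RIMKLA (-2.07) in the other. VENTX stayed higher under BMP4 (log2 change 2.05 early and 2.11 late), as did GOLIM4 (1.99 and 2.15, with dimmer probes at 1.23 and 0.45 late), whereas ZNF121 was lower late (-1.37). The log2 level of ZNF121 was 6.67 on the untreated day 0 array and 8.505 to 9.23 on later untreated arrays. The BMP and SMAD list had a median day 0 difference of 0.22. POU5F1, SOX2 and NANOG differed by -0.30, -0.09 and 0.99.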

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

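The tests that weigh explanations for the 3 patterns at the end of this part were chosen after those results were seen; the exchange of days for the difference between windows was added later as well; the other comparisons with splits of the arrays, the search for distant arrays and the test of late against early effects were set before.

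The late effect differed from the early one in 54 of the 122 named genes. Over all 13339 genes it did in 1237 (9.27%). Named genes were chosen for large changes, some of them for this very difference, so their higher share follows from the choice. The late log2 change was the higher one by 4.75 in LUM, 4.65 in SLC39A2, 4.45 in MYL4, 4.41 in HOPX, 4.40 in COL3A1, 4.38 in NPY, 4.34 in COL6A3, 4.30 in SNAI2, 4.09 in UGT2B11, 3.82 in GABRP, 3.65 in HOXB8, 3.64 in PITX1, 3.62 in IGFBP3, 3.45 in HAND2, 2.90 in HOXB5, 2.86 in TCIM, 2.85 in HOXB2, 2.56 in COL5A1, 2.39 in HAPLN1, 2.35 in GADD45G, 2.27 in COL4A2, 2.25 in TEK, 2.07 in LMO2, 2.06 in NCAM1, 2.06 in COL4A1, 1.88 in CDKN1C, 1.84 in GATA4, 1.79 in TBX3, 1.59 in DUSP6, 1.57 in MMP2, 1.43 in PGF, 1.39 in LEF1, 1.23 in SPRED2, 1.22 in ITGA5 and 1.07 in LAMB1. Late minus early was -0.72 in HPRT1, -0.96 in ZNF121, -1.24 in POU5F1, -1.38 in TAP1, -1.53 in LRIG1, -1.64 in PLAAT4, -1.68 in SOX3, -1.79 in PSMB8, -2.06 in EPHA4, -2.11 in OTX2, -2.14 in SOX2, -2.15 in SHISA2, -2.31 in IDO1, -2.60 in NODAL, -2.60 in FEZF1, -2.78 in RHBDL3, -2.94 in SOX21, -3.49 in CDH6 and -3.57 in SIX3. For SIX3, FEZF1 and EPHA4 the untreated arrays of days 4 to 7 enter both this difference and the drift, and 7 of the 577 genes with a lower late effect were also among the 10 that drifted upward. Where an arm was not above background in a window, as for SLC39A2, HOPX, HOXB8 and FEZF1, the value is not exact.

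In the 4 arrays of a late window, 12 of 244 groups of named genes had an array far from the other 3. Independent draws would give about that number (1 in 20). The arrays are ordered days and all genes share them, so that rate may not apply. Most of the distant arrays were of day 4, the first of the window, and a trend within the window was not told apart. The gap over the range was 0.991 for HSPA1A (untreated, day 4 high), 0.904 for SLCO2A1 (untreated, day 4 high), 0.860 for KRT16P2 (untreated, day 4 high), 0.858 for HOPX (untreated, day 6 high) and 0.847 for EGR1 (untreated, day 6 high). Under BMP4 it was 0.975 for NPTX1 (day 4 high), 0.965 for SNAI2 (day 4 low), 0.90 for TRIB3 (day 4 low), 0.899 for TCIM (day 4 low), 0.831 for TBX3 (day 4 low), 0.878 for PSG4 (day 7 high) and 0.874 for SLCO2A1 (day 7 low).

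Among 6245 detected probes without a gene name, 2458 differed late between the arms, 989 higher and 1469 lower with BMP4. They enter no comparison above.

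Of the 35 splits of the 8 late arrays 1, the real one, gave as many as 7230 genes, and the highest other gave 0. This argues against a chance sorting of the arrays, but not against another lasting difference between the arms. The other splits mix the arms, which widens their spread, and the days of an arm may not be independent. The same holds for days 1 to 7 (1 of 100 splits drawn, 7010 genes against 4817 at most in the others) and for the course (1 of 100, 8262 against 7864 in the split that exchanged the arms on every day but day 0). That last split keeps the arms whole from day 1 on, so the F test responds there to the same contrast. For the difference between windows, trading arrays between the arms decides nothing (1 of 100, 1237 against 1210), because mixing the arms widens the spread whether or not the windows differ. With the days exchanged in both arms alike 2 of 35 splits gave at least 1237 genes, so this test does not exclude chance. The other, which parts days 5 to 7 from days 1 to 4, gave 1612. It also sets late days against early ones, so the test cannot tell chance from the same change with a later boundary. The 6 early arrays make only 10 splits, too few for a share under 0.05, with 3930 genes in the real one and 0 at most in the others. For the drift of untreated cells 2 of 35 splits gave at least 10 genes, so this test does not exclude chance. The other, which parts days 5 to 7 from days 1 to 4, gave 16. It follows the order of the days as well, so the test cannot tell chance from a trend in time with a later boundary.

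The pair of day 0 arrays was at least 2-fold apart in 1024 genes. A full BMP4 response in the day 0 sample is argued against by the BMP and SMAD list, whose median day 0 difference was 0.22 against 2.61 early. A brief exposure stays open. ID1 and SMAD7 were over 1.5-fold higher and above all untreated arrays from day 0 on, and no other member of that list was. An untreated day 0 array that stands apart is argued against as the whole cause, since it alone lay outside the range of later untreated arrays in 23.4% of these genes, the BMP4 day 0 array alone in 28.6% and both in 46.5%, but it stays open for part of them, as that array differed from later ones of its arm with an SD of 0.466 to 0.592. A constant offset between the cultures stays open for part of the genes, since 33.1% of these genes kept the sign and at least 50% of the size on days 1 to 7, and with an unknown number of cultures it cannot be told apart from an effect of BMP4 in those genes. No biological explanation beyond BMP4 was tested.

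SOX2 fell further than POU5F1 under BMP4. The late changes differed by -2.55 on the log2 scale (by day SOX2 -4.06 to -2.94, POU5F1 -1.50 to -0.50). Dilution by cells without either transcript would lower both alike and leave no gap, if the probes read those transcripts alone. The gap is itself the pattern to be explained, so its size is no separate test of dilution. Whether dilution had a part in the falls themselves stays open. Background as the cause is argued against, since correcting it moved the late POU5F1 change by -0.0428. A probe that also reads POU5F1 pseudogenes stays open: the second probe lies near background at a mean intensity of 141 and gave -0.11. SOX2 stayed over 2-fold lower from day 2 on and POU5F1 from day 5 on. On days 5 to 7 SOX2 differed by -3.92, -4.06 and -3.84. POU5F1 differed by -1.32, -1.50 and -1.24 on those days, so the gap had not closed by day 7. An earlier response of SOX2 than of POU5F1 to BMP4 may account for part of the pattern and remains a hypothesis.

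The neural list had a median drift of 0.51 in untreated cells, with 1 of 12 genes past the test and adjusted p = 0.605 with an estimated correlation, so whether the list moved as a group is not settled. Of 10000 random lists matched on level 0.01% drifted as far, the smallest share they can give. This cannot judge a growing offset of the whole arm, because quantile normalization removes a shift common to all genes beforehand. The random lists also lack the correlation among the neural genes. Dependence on 1 array stays open: without untreated day 7 the list median was 0.26 in place of 0.51, which neither keeps nor ends the shift. A slow start of neural differentiation without BMP4 could be the source, and the labels name no treatment that tests it.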

How the results depend on the processing

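Tests with the day 0 difference subtracted, an offset of 50, centring on housekeeping genes, the shape of the course and both day 7 arrays left out were chosen after the data were seen; the others were planned. Counts of calls that stayed within 1.5 times under an alternative are not listed. With the day 0 difference subtracted the counts became 316 early, 2612 late and 366 over days 1 to 7, in part because 1 array per arm at day 0 enlarges the error. The window of days 1 to 2 gave 2360 early genes from fewer arrays, and the course tested for shape alone gave 3620. Array weights, whose fit did not fully converge, gave 3583 genes for the difference and 183 for the drift. The drift gave 1 gene on deposited log2 values without background correction and 3 with an offset of 50; the cause was not tested. The SD of the day 0 difference was 0.312 on those log2 values. Leaving out 1 array gave 2874 to 3954 early genes, 6587 to 7323 late, 678 to 2404 for the difference, 1 to 28 for the drift, 6470 to 7368 over days 1 to 7 and 7510 to 8791 for the course.

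Scaling arrays to 1 median moved nothing, because quantile normalization had already made the medians equal. Centring on the housekeeping list shifted the median of all genes by 0.18 in the late window and raised the share of higher calls from 54.8% to 68.2% early, from 50.6% to 66.8% late, from 53.4% to 63.8% for the difference and from 52.5% to 67.9% over days 1 to 7. It turned the early cell cycle median to 0.0779 and the late housekeeping median to 0.00745. Log2 values without background correction and the authors' values as given are the same here, and the intended neqc was not run.

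Subtraction of day 0 turned the early changes of NANOG (-0.68), IGFBP2 (0.11) and DUSP4 (0.59), the late changes of PSG4 (-0.0880), EDNRB (-0.32), GRHL2 (-0.31) and ANKRD37 (0.0867), the early medians of the blood (-0.19), cell cycle (0.0206) and housekeeping (0.12) lists, and the late medians of the neural crest (-0.27), hypoxia (0.0426) and interferon (-0.0551) lists. Other list medians near 0 that changed sign were the early placental list without a filter (-0.00677), the early endoderm list above the floor on 1 array (-0.0105), the late neural crest (-0.0131) and stress (-0.0158) lists with the mean of probes, and with array weights the early blood (-0.0252), cell cycle (0.0605) and interferon (-0.11) lists; the cause was not tested. Leaving out 1 array, early medians ranged from -0.0112 to 0.25 for the placental, -0.0788 to 0.27 for the extravillous, -0.22 to 0.13 for the endoderm, -0.0510 to 0.16 for the blood, -0.0774 to 0.0779 for the cell cycle, -0.0818 to 0.0802 for the interferon and -0.44 to 0.0126 for the pluripotency list, and the late interferon median from -0.0200 to 0.11.

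Outside leave-one-out, 1972 of the values of named genes kept direction and call, 54 lost the call (38 of them with day 0 subtracted), 1 gained it and 7 turned. For gene lists 501 kept both, 24 lost the call (19 of them with an estimated correlation), 10 gained it and 15 turned. Leaving out 1 array, 1054 values of named genes kept the call and 29 lost it, mostly NODAL, SIX3, FEZF1, EPHA4 and VWF in the difference or the drift. Of the list values 319 kept direction and call, 4 lost the call, 7 gained it and 20 turned.

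With day as the replicate block 3990 genes passed early, 7185 late, 1370 for the difference and 7060 over days 1 to 7. Arrays of the same day deviated together little on most days (correlations of -0.04 to 0.29 over days 1 to 7, the highest on day 2). Of the 7 BMP4 arrays 2 correlated best with the untreated array of their own day. With 1 array per arm and day, these values do not settle whether samples of a day shared more than its number. Signal over background limits genes near the floor of 134.7, such as most placental genes.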

Other observations

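The genes below were singled out after their values were seen, as were the groupings.

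SLCO2A1, the prostaglandin transporter gene, rose 25.3-fold early and 39.5-fold late. HPGD, the gene of an enzyme that inactivates prostaglandins, was at least 21.3-fold higher early and at least 11.2-fold late, with a log2 difference of 1.45 between the arms at day 0 already. HPGD was not above background on the untreated day 0 array, so that difference is not exact. BMP4 itself, a member of the amnion list, was at least 7.27-fold higher in the treated cells early and at least 15.8-fold higher late. The BMP antagonist gene NOG was at least 2.58-fold higher early and at least 2.75-fold late, and BMPER, which encodes a BMP-binding protein, rose at least 18.1-fold late. The antagonist gene GREM1 rose early (log2 change 1.33) and had a log2 change of 0.45 late, a difference between windows that did not pass (adjusted p = 0.253).

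Genes of antigen processing and presentation moved both ways. PSMB8 fell by 2.17 and TAP1 by 1.28 late on the log2 scale (log2 changes of -2.17 and -1.28), and HLA-B by 1.03 (log2 change -1.03), whereas HLA-E (1.19) and B2M (1.27) rose. Interferon-induced genes such as ISG15 (0.23) and IFIT3 (0.11) did not pass the test, while IFITM1 (0.36), IFITM2 (0.66) and IFITM3 (0.52) rose. DUSP6, a feedback phosphatase gene of ERK signalling, fell early by 1.22 (log2 change -1.22) and had a log2 change of 0.37 late on its brighter probe and 0.99 on its other one, with a difference of 1.59 between the windows (adjusted p = 0.00706). At day 0 it was already 1.18 lower (log2 difference -1.18).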
